A study of Mus musculus with 51 samples.

How the data were processed

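RNA was measured in neurons sorted by fluorescence-activated cell sorting from adult mouse midbrain, with Smart-seq2 libraries, per the labels' protocols. The authors deposited 1 table of raw read counts per gene for 51 libraries, with 24564 genes and 1 column per library. Reads had been aligned with STAR 2.7.0a to mm10 (GRCm38), per the submitters' processing notes; the counting tool, its settings and its use of strand are not given in the sources used here. Smart-seq2 reads carry no molecular tags as counted here, so floors and counting intervals cover counting error alone. No sample column was left out (0 unused) and 0 pairs of columns were identical. Chi-square per degree of freedom between replicates of a group, over genes with at least 20 counts in a pair, was 6.98 or more. A row for the mCherry reporter, at most 0.00294% of a library's counts, was kept out of tests. Sex by Xist and Ddx3y counts matched the label in 51 of 51 libraries.

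Group, age, genotype, sequencing set and sex were taken per the labels, and replicates are separate animals by their numbers. Total counts per library were 3500770 to 5337848 in mDA wt and 1654667 to 4587312 in mDA mutants at 4 months, and 1644460 to 12250492 and 4312167 to 11896342 at 8 months. In 5HT they were 3211468 to 5602332 in wt and 2795515 to 6047882 in mutants at 4 months, and 4894911 to 6344738 and 5568472 to 6369421 at 8 months. Coordinates are those of RefSeq for GRCm38.p6, matched by symbol for 22460 of 24564 genes (91.4%).

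Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr by group with a minimum count of 10, a robust quasi-likelihood fit, and Benjamini-Hochberg adjusted p under 0.05 for a call. The 35 mDA libraries were fitted together, with sequencing set within age and sex as terms, and the 16 5HT libraries together with sex as a term. The difference between the effects at 8 and 4 months was a contrast in each fit, and the difference between cell types came from a fit of all 51 libraries. The wt cell types were compared in the 25 wt libraries with sex as a term, and the mDA wt ages with the set label shared over ages. The biological coefficient of variation was 0.403 in the mDA and 0.546 in the 5HT fit. SE values are the absolute log2 fold change divided by the square root of F and are approximate. Overlaps of calls were tested with Fisher's exact test, which treats genes as independent. Its p-values therefore do not measure a difference between animals. A gene without wt counts is given as at least N-fold higher against a floor of 3 counts over the group, and a gene with 1 to 3 wt counts as a ratio with its 95% counting interval.

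Fixed gene lists were tested with camera (limma 3.58.1) at its preset correlation and with an estimated one, adjusted over the lists of a comparison with at least 3 tested members. The lists covered dopamine and serotonin synthesis and handling, dopaminergic and serotonergic transcription factors, substantia nigra and ventral tegmental type markers, HOX clusters, other developmental transcription factors, CDK inhibitors, PRC1 and PRC2 subunits, signalling ligands of the WNT, BMP and hedgehog families, ion channels, transmitter receptors, presynaptic genes, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, familial parkinsonism genes, cell death and p53 response genes, immediate early genes, imprinted genes, sex check genes, and markers of GABA, glutamate, noradrenergic and cholinergic neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, ependymal and choroid cells and erythroid cells. The lists overlap in part: Ddc, Slc18a2 and Maob are in both transmitter lists, and En1 and Foxa2 in both factor lists. Genes enriched in either wt cell type were taken from the other age (adjusted p under 0.01, absolute log2 fold change over 2). The tests, terms, lists, most other settings and the rule for named genes were fixed before the data were examined.

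Named genes were Eed; per genotype comparison the 8 largest changes on each side among called genes with a mean log2 CPM of at least 1, leaving out gene models, Y-linked genes and Xist; up to 4 called members with the smallest p per list; 5 per side with the smallest p in the other comparisons; and Th, Slc6a3, Slc18a2, Ddc, Nr4a2, Pitx3, Tph2, Slc6a4, Fev, Cdkn2a, Cdkn2b and Cdkn1a throughout. A few genes that this rule selects are not reported here.

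The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. Of these edgeR recovered 59% and 85% in mDA at 4 months (5 false of 149 calls), 48% and 65% in mDA at 8 months (3 of 116), 16% and 64% in 5HT at 4 months (3 of 83) and 10% and 51% in 5HT at 8 months (2 of 63), with 0 wrong signs. In the same order DESeq2 made 22 false of 176 calls, 16 of 143, 39 of 144 and 24 of 104. Of 20 lists without change, 0 passed. The simulated genes varied independently of each other, so this cannot show how camera's preset correlation performs on lists whose members vary together.

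The analysis was repeated with DESeq2 1.42.0, limma voom with sample weights, RLE scaling, no filter, a test against a 1.5-fold change, no sex term, no batch term, a shared batch label, the number of detected genes as a term, the compared groups alone, set1 or set2 alone, each 5HT library left out in turn, and for lists and overlaps another correlation, threshold or tool. Settings chosen after the data were seen left out the 4 mDA set1 mutants of 4 months, library C250, libraries S369 and S427, or C250 with these, used library totals without TMM, or added the share of the 10 most abundant genes or the summed astrocyte and endothelial marker level as a term. Counts of calls under these settings were compared per direction, a form chosen after the counts were seen. They were also set against up to 100 other splits of the same libraries.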

Results

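Gene expression was measured by RNA-seq (Smart-seq2, a full-length method for low RNA input) in neurons isolated from the midbrain of adult mice by fluorescence-activated cell sorting. The question was how gene expression changes when such neurons lack a working Polycomb repressive complex 2 (PRC2), the complex that methylates lysine 27 of histone H3. Midbrain dopaminergic (mDA) neurons came from a DatCre line and serotonergic (5HT) neurons from a SertCre line, and in each line the labels set mutants of Eed, a core PRC2 subunit, against wt animals. The 51 libraries fell into 8 groups. The mDA groups held 9 wt and 10 mutant libraries at 4 months and 8 wt and 8 mutant libraries at 8 months, and each of the 4 5HT groups held 4 libraries. Each library came from 1 animal, and no label paired wt with mutant animals. Total counts per library ran from 1644460 to 12250492. The floor of 3 counts stood for 0.245 to 1.82 CPM, the count scaled to a library total of 1000000. All levels are CPM on TMM-scaled library sizes, given as mean ± SD over libraries. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. "Higher" or "lower" compares labelled mutants with wt unless another pair is named. The labels gave 3 sequencing sets for mDA and 1 for 5HT. At 4 months the mDA set1 wt animals were all male and the set1 mutants all female, and set3 held the reverse.

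Eed itself (chromosome 7, 89954654 to 89980976, GRCm38) was not lower in the labelled mutants. In mDA neurons its level was 23.9 ± 9.56 CPM (n = 10) in labelled mutants against 14.0 ± 6.29 (n = 9) at 4 months (log2 fold change 0.74, edgeR adjusted p = 0.114), and 22.4 ± 9.33 (n = 8) against 13.4 ± 3.13 (n = 8) at 8 months (0.60, adjusted p = 0.271). In 5HT neurons it was 24.8 ± 3.65 against 10.2 ± 3.1 at 4 months (log2 fold change 1.29, adjusted p = 0.554) and 17.8 ± 5.6 against 13.6 ± 2.18 at 8 months (0.38, adjusted p = 1), with n = 4 in every group. Single mDA libraries ranged from 13.1 to 40.1 unscaled CPM in mutants and from 6.82 to 26.3 in wt at 4 months, and from 9.08 to 37.3 and from 8.13 to 17.6 at 8 months. Single 5HT libraries ranged from 21.5 to 29.9 in mutants and from 7.16 to 14.3 in wt at 4 months, and from 13.5 to 26.1 and from 11.3 to 15.5 at 8 months. A count over the whole gene cannot isolate deleted exons and so checks no label. Every direction below therefore rests on the labels, and "mutant" stands for "labelled mutant".

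The wt neurons of the 2 cell types were compared first, as the baseline against which identity genes are read. In mDA neurons Th (tyrosine hydroxylase, rate-limiting for dopamine synthesis) was higher than in 5HT neurons by 6.90 on the log2 scale (SE 0.26, adjusted p = 1.11e-20). So were the nicotinic receptor subunit genes Chrna6 (7.67) and Chrnb3 (7.28), the neurotensin receptor gene Ntsr1 (7.54) and Phldb2 (5.50). In 5HT neurons the serotonin transporter gene Slc6a4 was higher (-10.18 for mDA against 5HT, SE 0.36, adjusted p = 8.53e-18). So were the organic cation transporter gene Slc22a3 (-6.13), the monoamine oxidase gene Maob (-4.80), the glucocorticoid receptor gene Nr3c1 (-2.86) and Fryl (-2.0). Of 16178 genes tested in the 25 wt libraries, 3513 differed, 1835 higher in mDA and 1678 higher in 5HT. Cell type, mouse line and sequencing set were confounded in this contrast.

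In mDA neurons at 4 months, mutants showed higher levels of developmental regulators, while the genes of dopamine synthesis and transport were not called. Shox2, a homeobox gene, rose from 3.2 ± 2.36 CPM in wt (n = 9) to 36.7 ± 8.82 in mutants (n = 10), a 12.9-fold change (log2 fold change 3.69, SE 0.27, adjusted p = 4.64e-13). The long non-coding RNA Dleu2 rose from 0.95 ± 0.731 to 15.5 ± 4.96 CPM (log2 fold change 3.99, adjusted p = 7.64e-09). Whether the counting used strand was not given in the sources used here, so this count can include reads of an overlapping gene. Among the lower genes were Myo7a, which encodes an unconventional myosin (23.1 ± 12.5 CPM in wt, 3.31 ± 1.7 in mutants, log2 fold change -2.78, adjusted p = 0.000243), and Scg5, which encodes a secretory granule chaperone (366 ± 146 and 163 ± 79.2 CPM, log2 fold change -1.13, adjusted p = 0.00335). Levels of Th (1680 ± 591 CPM in mutants, 1890 ± 409 in wt), Slc6a3 (the dopamine transporter, 2620 ± 770 and 2520 ± 839), Slc18a2 (the vesicular monoamine transporter, 1770 ± 400 and 2100 ± 354) and Ddc (aromatic amino acid decarboxylase, 717 ± 258 and 723 ± 197) had adjusted p-values of 0.648, 0.555, 0.18 and 0.885.

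Of 108 tested developmental transcription factor genes outside the HOX clusters, 15 rose and 0 fell at 4 months in mDA neurons, or 32 rose when adjusted over the list alone, and 91 had a positive log2 fold change (median 1.12). Foxd3, a neural crest regulator, had 2 counts in all wt libraries together, and mutants stood at a ratio of 65.4 (95% counting interval 17.7 to 547; adjusted p = 2.54e-05). Pitx1 (log2 fold change 3.87), Barx1 (3.27), Tbx1 (4.58) and Foxf2 (3.77) rose too. Of 22 tested HOX genes, the body-axis regulators, 3 rose and 0 fell (5 rose when adjusted over the list alone): Hoxc8 (3.12), Hoxa7 (2.64) and Hoxa10 (2.38), all at wt levels under 1 CPM. Of 21 genes for subunits of PRC1, the partner Polycomb complex, 3 rose and 0 fell (4 rose when adjusted over the list alone), among them Cbx8 (1.61) and Ring1 (0.91). Of 14 immediate early genes, the rapid response genes of neuronal activity and of tissue dissociation, 3 rose and 0 fell (6 rose when adjusted over the list alone): Fosl2 (2.56), Egr1 (1.28) and Nr4a1 (1.09). The camera test of each of these 4 lists against all other genes passed at the preset correlation and with an estimated one (adjusted p = 1.73e-06 for developmental factors, 0.0138 for HOX, 0.0431 for PRC1 and 0.000717 for immediate early genes, each with an estimated correlation).

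Other groups in mDA neurons at 4 months had few or 0 called members. Gad1, which encodes a GABA-synthesizing enzyme, rose from 44.6 ± 13.6 to 76.7 ± 29 CPM (log2 fold change 0.79, adjusted p = 0.0178), although within set1 alone its direction turned (-0.14, adjusted p = 0.696). It was the 1 called of 5 GABA neuron markers (1 higher and 1 lower when adjusted over the list alone). Gata2, a serotonergic and GABAergic regulator, was the 1 gene of 10 serotonergic transcription factors called (2.24, adjusted p = 0.00165; 1 when adjusted over the list alone). The list test was at adjusted p = 0.0238, or 0.15 with an estimated correlation. Of 10 markers of the substantia nigra type of dopamine neuron, Kcns3 (0.69) and Satb1 (0.48) rose and 0 fell (2 rose when adjusted over the list alone). Of the 14 markers of the ventral tegmental type, 0 were called (2 fell when adjusted over the list alone). Their median was -0.40, with a list test at adjusted p = 0.000598, or 0.15 with an estimated correlation. The 16 dopamine synthesis and handling genes had 0 calls (4 fell when adjusted over the list alone), a median of -0.15 and a list test at adjusted p = 0.0133, or 0.33 with an estimated correlation. For the 15 oligodendrocyte markers the median was -0.60 and the list test was at adjusted p = 3.24e-06, or 0.15 with an estimated correlation. Summed CPM of oligodendrocyte markers was 775 ± 311 in mutants and 1170 ± 432 in wt. For astrocyte markers the sums were 609 ± 197 and 764 ± 102, for microglia markers 61.5 ± 19.7 and 89.2 ± 28, and for endothelial and mural markers 54.5 ± 21.9 and 49.5 ± 8.86.

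In all, 181 of 15425 genes were called in mDA neurons at 4 months, 89 higher and 92 lower, and 2238 had an unadjusted p under 0.05. Within set1 alone the same contrast, in which sex equals genotype, called 2069 genes (788 higher, 1281 lower). Within set2 alone it called 5 (5 higher, 0 lower), while set3, with 2 animals per genotype, was not fitted alone. HOX genes had 3 calls of 29 within set1 and 0 of 30 within set2. The other developmental factors had 22 higher and 1 lower of 120 within set1 and 1 higher and 0 lower of 131 within set2, where 112 were positive. Without the 4 set1 mutants, an alternative added after the data were seen, 20 genes were called (19 higher, 1 lower). All 89 higher calls stayed positive and 18 stayed called, and all 92 lower calls stayed negative and 1 stayed called. The kept signs follow in part from the choice of these genes, which used the remaining libraries too. Shox2 (4.39), Dleu2 (4.15), Pitx1 (3.96), Tbx1 (6.70), Cbx8 (1.86), Gad1 (1.37) and Foxd3 (2 wt counts, adjusted p = 0.00218) were called there as well. The 3 HOX genes, Barx1, Foxf2, Myo7a, Scg5, Gata2, Ring1, Kcns3, Satb1 and the 3 immediate early genes had adjusted p-values from 0.0671 to 0.656. With RLE scaling the split was 96 higher and 56 lower, by DESeq2 206 and 146, and without a term for the set 44 and 13.

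In mDA neurons at 8 months, mutants had lower levels of the genes of dopamine synthesis and transport and higher levels of HOX genes, other developmental regulators and GABA neuron markers. Slc18a2 (chromosome 19, 59260878 to 59296012) was 737 ± 66 CPM in mutants and 2130 ± 370 in wt (n = 8 each), 2.81-fold lower (log2 fold change -1.49, SE 0.10, adjusted p = 8.64e-15). Slc6a3 (chromosome 13, 73536128 to 73578672) was 1110 ± 217 and 2810 ± 470 CPM (-1.40, SE 0.14, adjusted p = 8.5e-10), and Th (chromosome 7, 142892779 to 142899995) was 722 ± 104 and 1690 ± 341 CPM (-1.22, SE 0.12, adjusted p = 2.17e-09). Ddc was 555 ± 88.9 and 708 ± 128 CPM and was not called (-0.37, adjusted p = 0.109). Gad1 (chromosome 2, 70561303 to 70602014) rose from 44.2 ± 19.5 to 284 ± 54.5 CPM (2.76, SE 0.23, adjusted p = 6.85e-12).

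Of 16 dopamine synthesis and handling genes, 5 fell and 0 rose (7 fell and 1 rose when adjusted over the list alone), the other 2 being Slc10a4 (-0.64) and the autoreceptor gene Drd2 (-0.61). Of 12 dopaminergic transcription factors, 5 fell and 0 rose (6 fell when adjusted over the list alone). En1 was 40.9 ± 9.62 CPM in mutants and 116 ± 22.7 in wt (-1.54, adjusted p = 2.17e-09), and Pitx3 (-1.56), Ebf3 (-0.92) and Nr4a2 (-0.53) were among the others. Of 10 substantia nigra type markers, 6 fell and 0 rose (8 fell when adjusted over the list alone). Among them were Anxa1 (27.4 ± 10 to 5.87 ± 5.63 CPM, -2.48), Ndnf (-1.38), Kcns3 (-0.74) and Satb1 (-0.70). Of 14 ventral tegmental type markers, Calb2, a calcium buffer gene, rose (1.22) and Crhr1, a stress peptide receptor gene, fell (-0.67), or 3 rose and 1 fell when adjusted over the list alone. The first 3 lists had camera adjusted p-values of 0.0132, 0.00069 and 0.000328 with an estimated correlation, and the ventral tegmental list 0.931. The 306 genes higher in wt mDA than in wt 5HT neurons of the other age had 58 lower and 3 higher members (80 and 6 when adjusted over the list alone). Their median was -0.36, with adjusted p = 5.61e-07 with an estimated correlation. The 104 tested genes of the opposite list, higher in wt 5HT, had 13 higher and 0 lower members (16 and 0 when adjusted over the list alone). Their median was 0.36, with adjusted p = 0.000882 with an estimated correlation.

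**Figure D1:**
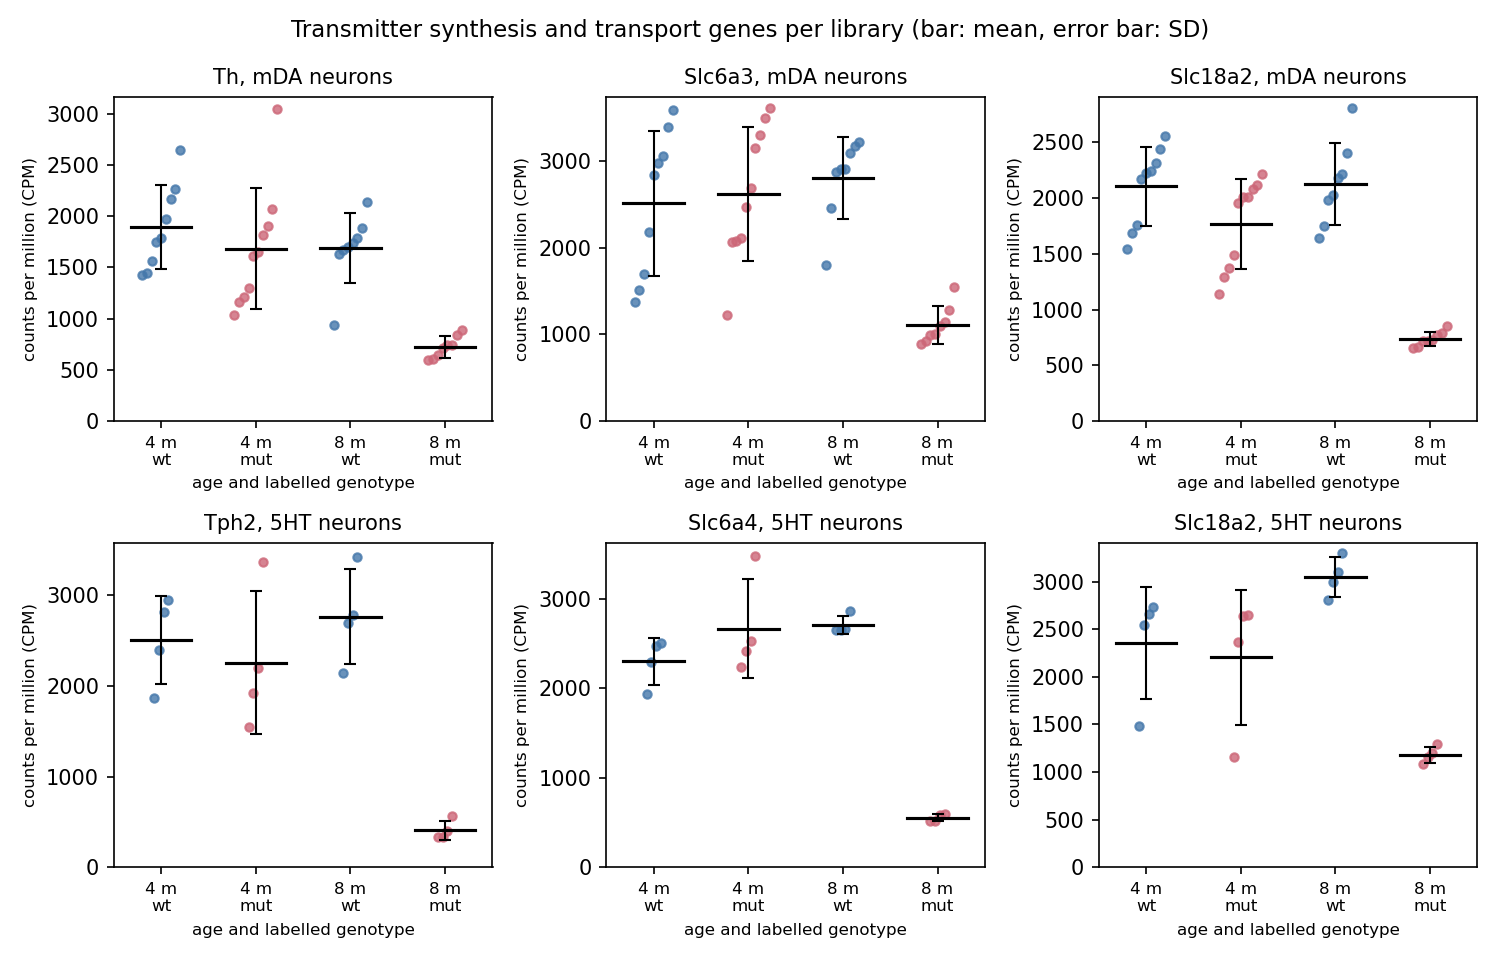
Levels in CPM (vertical axes, linear, from 0) of 3 transmitter synthesis and transport genes in mDA libraries (top) and 3 in 5HT libraries (bottom), by age and labelled genotype (m: months; points: libraries; bars: mean; error bars: SD). At 8 months mean Slc18a2 was 737 in mDA mutants and 2130 in wt, and mean Tph2 was 406 in 5HT mutants and 2770 in wt.

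All 22 tested HOX genes rose at 8 months in mDA neurons, with a median log2 fold change of 5.95, and all 22 also rose when adjusted over the list alone. They lie in clusters on chromosome 6 (Hoxa, 52155367 to 52260880), chromosome 11 (Hoxb, 96194316 to 96368254), chromosome 15 (Hoxc, 102921131 to 103036856) and chromosome 2 (Hoxd, 74668225 to 74765142). Summed HOX CPM was 512 ± 190 in mutants and 15.4 ± 14 in wt, where C250 stood at 49 and the other 7 wt libraries at 5.69 to 15.7. Hoxd11 rose from 0.0967 ± 0.104 to 37.5 ± 10.9 CPM (7.53, adjusted p = 4.49e-12) and Hoxc8 from 0.435 ± 0.497 to 52.7 ± 22.9 (6.14, adjusted p = 9.53e-10). Of the 108 other developmental factors, 60 rose and 0 fell (77 rose and 3 fell when adjusted over the list alone), with a median of 2.92. Pax6, a neural progenitor and eye regulator, rose from 6.95 ± 3.63 to 84.2 ± 19.7 CPM (3.92, adjusted p = 1e-11), and Tbx3 (5.11), Pitx1 (6.12) and Shox2 (2.93) rose as well. Foxd3 had 1 wt count and 556 mutant counts, a ratio of 421 (95% counting interval 75.2 to 16600). The non-coding RNA Vax2os rose from 1.33 ± 1.33 to 197 ± 115 CPM (7.80, adjusted p = 6.64e-17). The limit given for Dleu2, an unknown use of strand, holds for it at both ages and in both cell types. Of the CDK inhibitor genes, 1 of 5 tested rose (1 when adjusted over the list alone), Cdkn2b, from 0.48 ± 0.511 to 11.3 ± 5.54 CPM (5.18, adjusted p = 0.000825). The list test was at adjusted p = 0.0384, or 0.0727 with an estimated correlation. Cdkn2a was too low to be tested (3.01 ± 2.13 CPM in mutants, 0.154 ± 0.216 in wt), and Cdkn1a was not called (-0.25, adjusted p = 0.808).

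**Figure D2:**
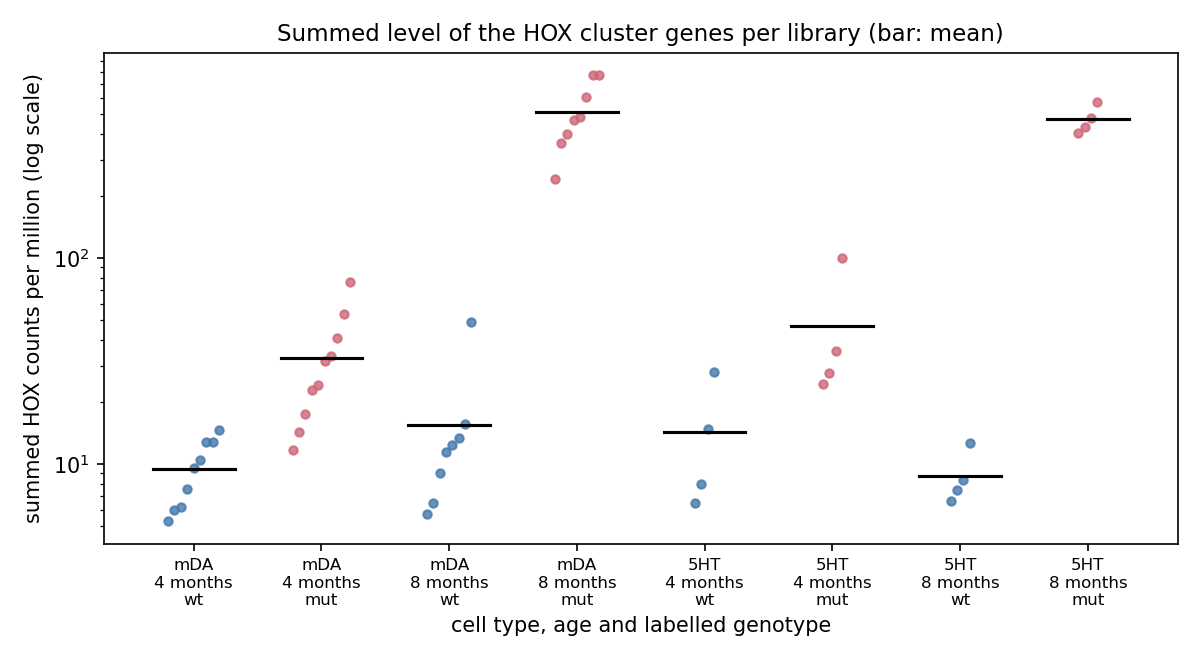
Summed CPM of the HOX cluster genes per library (vertical axis, log scale) by cell type, age and labelled genotype (points: libraries; bars: mean). At 8 months the mDA mutants lay between 243 and 770 and the mDA wt between 5.69 and 49, and the 5HT mutants lay between 404 and 570 and the 5HT wt between 6.59 and 12.7.

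Of 5 GABA neuron markers, 4 rose and 0 fell at 8 months in mDA neurons (5 rose when adjusted over the list alone; adjusted p = 2.93e-07 with an estimated correlation). Slc6a5, the neuronal glycine transporter, rose from 1.16 ± 1.11 to 92.2 ± 34.6 CPM (6.09, adjusted p = 1.62e-12). Slc32a1, the vesicular GABA transporter, rose 3.69-fold (1.88), and Gad2, a further GABA-synthesizing enzyme, rose 1.65-fold (0.72). Of 10 serotonergic transcription factors, Gata2 (3.36), Nkx2-2 (3.58) and Fev (2.69) rose and En1 fell (4 rose and 2 fell when adjusted over the list alone). The list had a median of -0.25, a mean of 0.72 and a test in the upward direction at adjusted p = 0.8. Tph2 (5.8 ± 3.59 CPM in mutants, 5.84 ± 8.94 in wt) and Slc6a4 (1.83 ± 1.43 and 1.91 ± 1.2) were not called. Of 14 immediate early genes, 5 rose and 0 fell (8 rose when adjusted over the list alone), among them Fos (2.15), Egr1 (1.76) and Nr4a1 (1.32), with adjusted p = 0.000101 with an estimated correlation. Of 72 ion channel genes 1 rose and 5 fell (1 and 5 when adjusted over the list alone), including Scn3a (-0.63), Cacna1a (-0.89) and Kcnj6 (-0.83). Of 69 transmitter receptor genes 1 rose and 4 fell (5 and 4 when adjusted over the list alone), including Oprk1 (-1.13), Ntsr1 (-0.92) and Gria3 (-0.83). Of 42 presynaptic genes 1 rose and 6 fell (8 and 9 when adjusted over the list alone), including Cplx1 (-1.01) and Erc2 (-0.82). These 3 lists as wholes had camera adjusted p-values of 0.907, 0.725 and 0.907, and the presynaptic list had a positive median (0.14) and a downward test.

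A few markers of astrocytes, endothelial cells and the oligodendrocyte lineage were called higher in the same comparison, but none of these lists passed with an estimated correlation. Summed astrocyte markers were 1300 ± 809 CPM in mutants and 681 ± 232 in wt, with D176 at 3140 and the other mutants at 707 to 1560. Of 15 members 2 rose, Apoe (1.63) and Slc1a2 (0.50), or 8 when adjusted over the list alone (adjusted p = 2.86e-05, or 0.125 with an estimated correlation). Summed endothelial and mural markers were 450 ± 592 and 43.6 ± 29.5 CPM. Of 14 members 3 rose, Cldn5 (4.55), Slco1a4 (3.28) and Egfl7 (1.63), or 4 when adjusted over the list alone (adjusted p = 0.000965, or 0.271 with an estimated correlation). Among oligodendrocyte precursor markers 1 of 10 rose, Bcan (1.35; 1 when adjusted over the list alone; list adjusted p = 0.0287, or 0.0959 with an estimated correlation). Among oligodendrocyte markers 1 of 15 rose, Ermn (1.04; 2 when adjusted over the list alone; 0.0222, or 0.498 with an estimated correlation). Summed microglia markers were 93.9 ± 34 and 86.2 ± 20.4 CPM, with a median log2 fold change of -0.132 and 0 of 12 members called (0 when adjusted over the list alone).

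**Figure D3:**
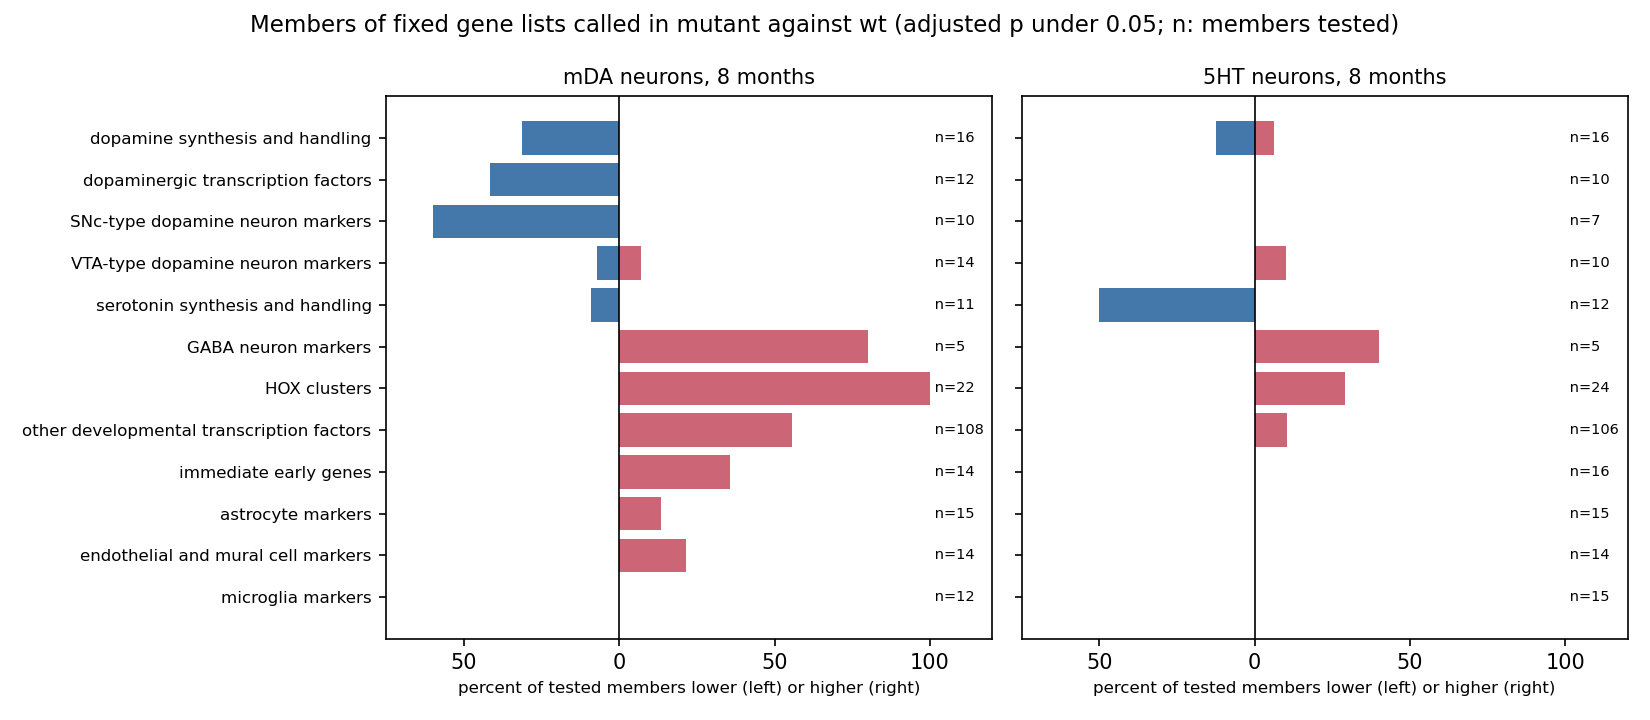
Percent of the tested members of 12 fixed gene lists that were called lower (bars to the left) or higher (bars to the right) in mutants against wt at 8 months, in mDA (left panel) and 5HT neurons (right panel); n is the number of members tested. In mDA neurons all 22 HOX genes were higher and 5 of 16 dopamine synthesis and handling genes lower; in 5HT neurons 7 of 24 HOX genes were higher and 6 of 12 serotonin synthesis and handling genes lower.

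In all, 666 of 15425 genes were called at 8 months in mDA neurons, 376 higher and 290 lower, and 2697 had an unadjusted p under 0.05. Among the genes with large falls were Derl3 (6.88 ± 2.86 to 0.435 ± 0.539 CPM, -4.27), Myo7a (28.3 ± 14.7 to 1.84 ± 1.35, -4.22), Vmn1r112 (3.28 ± 2.74 to 0.139 ± 0.156, -3.75) and Postn (11.3 ± 8.17 to 0.83 ± 1.02, -3.53). Several called rows that merge or repeat pheromone receptor genes of the Vmn1r family, noted after their values were seen, fell further than these. Within set1 alone 405 genes were called (249 higher, 156 lower) and within set2 alone 92 (68 higher, 24 lower); set3 held 2 wt libraries and no mutant. HOX genes had 25 calls of 29 within set1 and 9 of 30 within set2, all higher. The other developmental factors had 50 of 120 and 13 of 131, all higher. The dopamine synthesis and handling genes had 3 lower of 16 in both sets, with 1 higher in set1, and the GABA markers had 3 and 2 higher of 5. The astrocyte markers had 3 higher of 15 within set1 and 0 within set2, and the endothelial markers 0 of 14 within set1 (median -0.04) and 2 within set2 (median 3.90). Calls numbered 1434 by voom, 1060 by DESeq2, 393 without the sex term, 303 with the share of the 10 most abundant genes as a term and 208 with the astrocyte and endothelial marker level as a term, and the libraries of this age alone gave 229 higher and 154 lower. With that marker term Slc18a2, Slc6a3, Th and En1 were called, and Slc10a4, Pitx3, Ebf3, Drd2 and Nr4a2 were not (adjusted p = 0.0905 to 0.311).

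The genotype effect on mDA neurons was called as different between the ages for 580 genes with a more positive and 362 genes with a more negative effect at 8 months. Among the more negative were Slc18a2 (difference of log2 fold changes -1.28, SE 0.13, adjusted p = 1.04e-08), Slc6a3 (-1.56, SE 0.18), En1 (-1.54, SE 0.20), Th (-1.10, SE 0.16), Nr4a2 (-0.71, SE 0.19), Arhgap6 (-1.95, SE 0.22) and Fam184a (-1.66, SE 0.21). Among the more positive were Pax6 (3.52, SE 0.39, adjusted p = 1.31e-07), Slc6a5 (5.41, SE 0.62), Gad1 (1.97, SE 0.28), Wnt5a, a secreted signalling ligand gene (1.83, SE 0.25), and Hoxd11 (7.68, SE 1.1). For Shox2 the difference was not called (-0.76, adjusted p = 0.231), nor for Pitx3 (-1.37, adjusted p = 0.0563) or Gata2 (1.11, adjusted p = 0.291). Without the sex term 154 genes were called (66 more positive, 88 more negative), which turned the balance of directions. Without the 4 set1 mutants of 4 months 89 genes were called (36 more positive, 53 more negative). Of the main calls 34 of the 580 and 52 of the 362 stayed called, while all 580 and 360 of the 362 kept their sign, and of the genes named here Nr4a2 lost its call (-0.37, adjusted p = 0.443). The remaining libraries had helped to choose these genes, so the kept signs follow in large part from that choice. Of the genes called higher at 4 months in mDA neurons, 44 of 89 were called higher at 8 months too, where independent lists of the same sizes would share 2.17 (Fisher's exact p = 1.63e-47). This p-value treats genes as independent, although shared calls included members of 1 family or cluster, such as HOX genes and Xlr3a, Xlr3b and Xlr3c. Of the 92 called lower, 2 were called lower at 8 months too (Myo7a and Fdps, the latter named after its value was seen), where independent lists would share 1.73 (p = 0.519). The sign at 8 months was the same for 64 of the 89 and 28 of the 92.

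**Figure D4:**
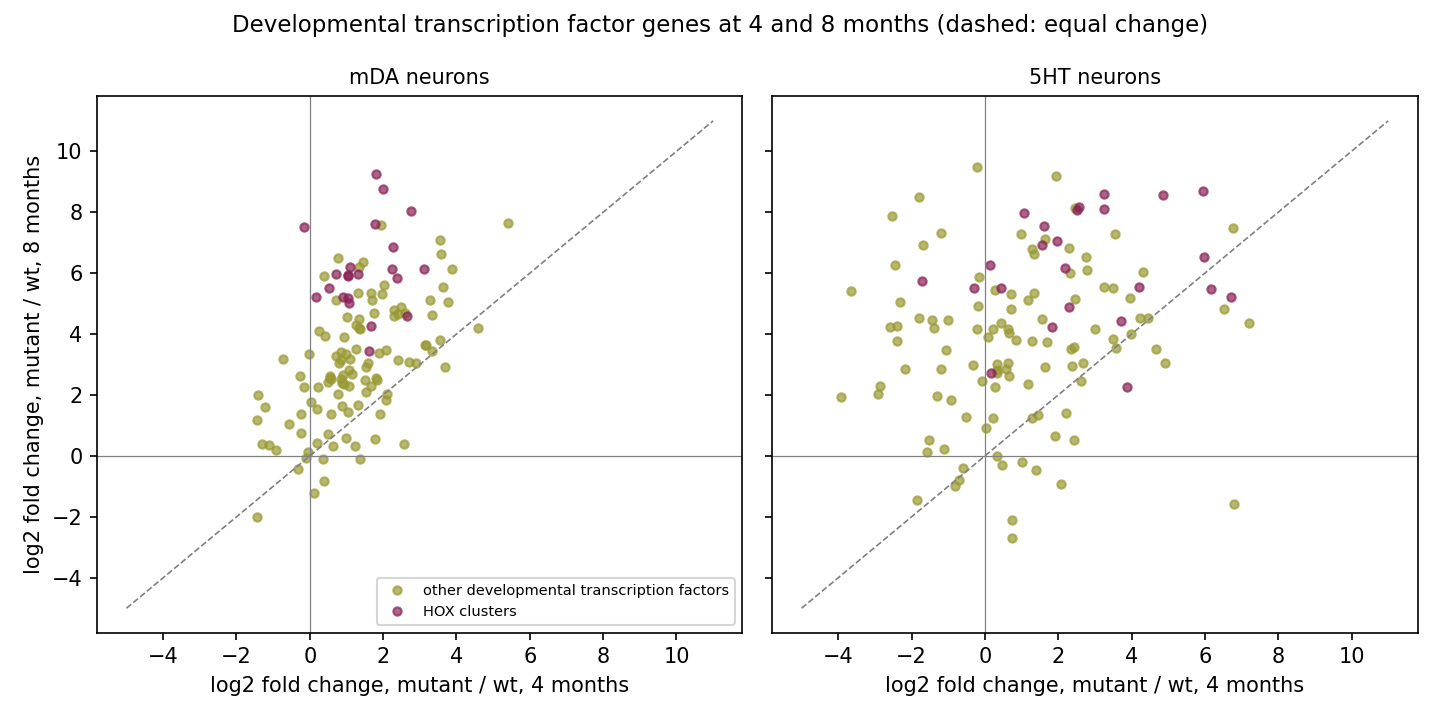
Log2 fold change of mutant against wt at 4 months (horizontal axis) and at 8 months (vertical axis) for each HOX gene and each other developmental transcription factor gene tested, in mDA (left) and 5HT neurons (right); the dashed line marks equal change. In mDA neurons the median log2 fold change of HOX genes was 1.47 at 4 months and 5.95 at 8 months.

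In 5HT neurons at 4 months 2 of 15633 genes were called, both higher in mutants. Tradd, which encodes an adaptor of tumour necrosis factor receptor signalling (chromosome 8, 105258575 to 105264594), had 0 counts in the 4 wt libraries and 148 in the 4 mutants (6.53 ± 3.07 CPM), at least 46.9-fold higher against a floor of 3 counts over the wt group (adjusted p = 0.0136). Amigo2, a neuronal adhesion molecule gene (chromosome 15, 97244074 to 97247287), rose from 35.9 ± 15.5 to 119 ± 39.5 CPM (log2 fold change 1.81, SE 0.28, adjusted p = 0.0136). Tph2, rate-limiting for serotonin synthesis (2260 ± 788 CPM in mutants, 2510 ± 483 in wt), Slc6a4 (2670 ± 554 and a mean of 2300, the wt libraries at 1930 to 2510), Slc18a2 (2210 ± 708 and 2360 ± 588), Ddc (864 ± 113 and 952 ± 120) and Fev, a serotonergic regulator (40.7 ± 9.83 and 54.2 ± 16.9), had adjusted p-values from 0.922 to 0.99. Of 24 tested HOX genes 0 were called over all genes and 5 rose when adjusted over the list alone, 22 had a positive log2 fold change (median 2.41, or 1.91 with the 7 genes without wt counts at their lower bound). The camera test passed (adjusted p = 0.0147 with an estimated correlation). Summed HOX CPM was 46.9 ± 35.8 in mutants, where S427 stood at 100 and the other 3 at 24.3 to 35.5, and 14.3 ± 9.8 in wt. Of the 106 other developmental factors 0 were called (2 rose when adjusted over the list alone), with a median of 0.68 and adjusted p = 0.00589, or 0.544 with an estimated correlation. Summed astrocyte markers had a mean of 714 CPM in mutants (390 to 901) and 749 in wt (471 to 1054). Endothelial and mural markers were 101 ± 38.8 and 85.6 ± 16 and microglia markers 63.5 ± 5.57 and 95.6 ± 28.7, with 0 members called in each list (0 when adjusted over the list alone).

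An unadjusted p under 0.05 was reached by 1001 genes in 5HT neurons at 4 months, and DESeq2 called 48 and voom 1. Calls numbered 0 when library S367 or S425 was left out, 1 without S374 and 4 without S369, S373 or S427, and 12 without both S369 and S427. Tradd missed the threshold without S367, S374 or S425 and Amigo2 without S367 or S425. With 1 library left out at a time Tradd stayed higher, and the log2 fold change of Amigo2 ran from 1.51 to 2.02.

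In 5HT neurons at 8 months, mutants had lower levels of the genes of serotonin synthesis and transport and higher levels of developmental regulators. Tph2 (chromosome 10, 115078641 to 115185022) was 406 ± 109 CPM in mutants and 2770 ± 524 in wt (n = 4 each), 6.79-fold lower (log2 fold change -2.76, SE 0.25, adjusted p = 9.79e-07). Slc6a4 (chromosome 11, 76998597 to 77032343) was 553 ± 42.3 and 2710 ± 105 CPM (-2.29, SE 0.17, adjusted p = 4.72e-08). The serotonin autoreceptor gene Htr1a fell from 143 ± 11 to 27 ± 9.22 CPM (-2.40, SE 0.30, adjusted p = 0.000184) and Slc18a2 from 3050 ± 206 to 1180 ± 84.1 (-1.37, SE 0.22, adjusted p = 0.00294). The non-coding RNA Vax2os rose from 1.34 ± 0.583 to 392 ± 103 CPM (8.19, SE 0.49, adjusted p = 1.11e-09).

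Of 12 serotonin synthesis and handling genes, 6 fell and 0 rose (9 fell when adjusted over the list alone), the other 2 being Htr5b (-2.19) and Ddc (-1.08). The camera test passed (adjusted p = 0.000117 with an estimated correlation). Gchfr, a regulator of tetrahydrobiopterin synthesis, fell from 129 ± 32.7 to 33.1 ± 10.8 CPM (-2.0, adjusted p = 0.00397). Of 8 serotonergic transcription factors 0 were called (2 fell when adjusted over the list alone), with a median of -0.62 and adjusted p = 0.00878, or 0.121 with an estimated correlation. Fev was 9.39 ± 5.33 CPM in mutants and 23.1 ± 10.6 in wt (-1.24, adjusted p = 0.384). The 16 dopamine synthesis and handling genes held 2 lower members, Ddc and Slc18a2, which serve serotonin as well, and 1 higher, Ret, a neurotrophic receptor gene (47.4 ± 6.63 to 229 ± 45.1 CPM, 2.40). On this list 5 fell and 2 rose when adjusted over the list alone, and the list test was at adjusted p = 0.0307, or 0.121 with an estimated correlation. Of the 117 genes higher in wt 5HT than in wt mDA neurons of the other age, 11 fell and 0 rose (26 and 2 when adjusted over the list alone), with a median of -0.40 and adjusted p = 5.02e-08 with an estimated correlation. Of 253 tested genes of the opposite list, higher in wt mDA, 4 rose and 0 fell (6 and 0 when adjusted over the list alone), with a median of 0.25 and adjusted p = 0.0133 with an estimated correlation.

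Of 24 tested HOX genes, 7 rose and 0 fell in 5HT neurons at 8 months, or 22 rose when adjusted over the list alone, and all 24 had a positive log2 fold change (median 6.21, or 5.51 with the 5 genes without wt counts at their lower bound). Summed HOX CPM was 472 ± 72.6 in mutants and 8.78 ± 2.71 in wt. Hoxd10 rose from 0.689 ± 0.765 to 97 ± 11.9 CPM (7.05, adjusted p = 0.000732). Hoxd11 was 55.7 ± 17.7 CPM in mutants with 3 wt counts (95% counting interval of the ratio 145 to 2070). Hoxc10 had 1 wt count and 605 mutant counts (ratio 576, interval 103 to 22800). Of the 106 other developmental factors, 11 rose and 0 fell (63 rose when adjusted over the list alone), with a median of 3.80. Among them were Tbx3 (6.80), Lhx6 (6.54) and Dlx1, which had 0 wt counts (at least 55.5-fold higher against 3 counts over the group). The CDK inhibitor genes had 0 calls of 6 over all genes and 3 higher when adjusted over the list alone. Cdkn2a was 5.62 ± 1.81 CPM in mutants with 2 wt counts (ratio 63.3, interval 17.2 to 528; adjusted p = 0.219) and Cdkn2b 13.5 ± 1.58 with 2 wt counts (ratio 153, interval 42.1 to 1270; adjusted p = 0.138). Of 5 GABA neuron markers, Slc6a5 (20.2 ± 21.9 to 122 ± 19.6 CPM, 2.98) and Slc32a1 (2.15) rose, or 5 when adjusted over the list alone. Summed glutamate markers were 117 ± 20.2 CPM in mutants and 46.2 ± 29.4 in wt (0 of 2 called, 1 higher when adjusted over the list alone). Noradrenergic and cholinergic markers summed to 15.1 ± 4.18 and 7.96 ± 2.8 CPM (0 of 5 called, 0 when adjusted over the list alone). Of 21 PRC1 genes Pcgf1 rose (1.71; 4 when adjusted over the list alone), and of 16 immediate early genes 0 were called (0 when adjusted over the list alone; median 1.12). The camera adjusted p-values with an estimated correlation were 1.42e-06 for HOX, 8.47e-05 for the other developmental factors, 0.00319 for CDK inhibitors, 0.000311 for GABA markers, 0.0196 for PRC1 and 0.009 for immediate early genes. Summed astrocyte markers were 1040 ± 87 CPM in mutants and 1040 ± 151 in wt, endothelial and mural markers 200 ± 70.3 and 172 ± 15.3, and microglia markers 117 ± 16.7 and 181 ± 33.6, with 0 members called in each list (0 when adjusted over the list alone).

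In all, 62 of 15633 genes were called in 5HT neurons at 8 months, 39 higher and 23 lower, and 766 had an unadjusted p under 0.05. DESeq2 called 124 higher and 52 lower, voom 206 and 88, and edgeR on the 8 libraries of this age alone 140 and 59. Leaving out 1 library gave 30 calls without S385 or S447, 32 without S383, 40 without S446, 41 without S382 and 86 without S427. Tph2, Slc6a4, Htr1a, Slc18a2, Gchfr, Vax2os, Hoxd10 and Hoxd11 kept their calls in each case. Ddc missed the threshold without S447, and Htr5b, Slc6a5, Slc32a1, Dlx1, Barx1, Hoxd8, Isl2, Adcyap1, Muc6 and Klk1b22 without 1 or more of the libraries. At 8 months 33 genes were called higher in both cell types, where independent lists would share 0.963 (Fisher's exact p = 6.07e-48). HOX genes were among them, and the overlap tests treat genes as independent. At that age 4 were lower in both, Slc18a2, Cpne7, Nwd2 and Smc2, where independent lists would share 0.417 (p = 0.000705); the last 3 were named after their values were seen.

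The genotype effect on 5HT neurons differed between the ages for 2 genes, Slc6a4 (difference of log2 fold changes -2.51, SE 0.23, adjusted p = 5.22e-06) and Tph2 (-2.62, SE 0.33, adjusted p = 0.000496), both more negative at 8 months. Slc18a2 (-1.28, adjusted p = 0.314) and Ddc (-0.95, adjusted p = 0.547) were not called, and 620 genes had an unadjusted p under 0.05. DESeq2 called 28 genes and voom 11.

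The genotype effect averaged over the ages differed between mDA and 5HT neurons for 47 of 18386 genes, 10 more positive in mDA and 37 more negative. Gata2 was more positive in mDA (difference of log2 fold changes 3.39, SE 0.37, adjusted p = 1.35e-08), as were Fev (3.05), Bcam (2.36), Stxbp2 (1.41) and Sympk (0.80). Tle2, a Groucho-type corepressor gene (-2.30, SE 0.25, adjusted p = 1.35e-08), Nr4a2 (-2.76), Ret (-1.67), Lama5 (-1.59) and Tradd (-4.11) were more negative in mDA. The Nr4a2 effect in mDA neurons was 0.18 at 4 months and -0.53 at 8 months. In 5HT neurons Nr4a2 was not called. With each 5HT library left out in turn it was 1.16 to 2.76 at 4 months and 3.16 to 4.12 at 8 months. The 5HT effect on Tradd at 8 months differed from that at 4 months by -6.59 (not called, adjusted p = 0.242). DESeq2 called 177 genes in this contrast.

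Between 4 and 8 months, 0 genes were called by edgeR in wt mDA neurons and 0 in wt 5HT neurons, with 1204 and 964 genes at an unadjusted p under 0.05. DESeq2 called 18 and 15 genes and voom 0 and 2. The mDA contrast assumed that a set label named the same sequencing run at both ages, which the labels do not state.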

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

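The tests of the 3 patterns weighed below were chosen after the results were seen, except that of sequence around Eed; the other splits of the samples were planned.

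Single libraries stood far from the rest of their group in 12 of 120 groups of values tested, where chance gives about 6. Among mDA wt at 8 months, C250 had a HOX sum of 49 CPM (others 5.69 to 15.7) and Th at 941 (1630 to 2140). Among mDA mutants, D176 had an astrocyte marker sum of 3140 CPM at 8 months (others 707 to 1560) and C213 had Th at 3050 at 4 months (1030 to 2070). Among 5HT wt at 8 months, S383 had Slc6a4 at 2870 CPM (2650 to 2670) and Htr1a at 126 (others higher, up to 150), and among the mutants S447 had an endothelial marker sum of 304 (153 to 179). Among 5HT wt at 4 months, S369 had 31.7% of its counts in the 10 most abundant genes (21.1 to 22.7), Slc18a2 at 1480 CPM (2550 to 2730) and Htr1a at 45 (124 to 134). Among 5HT mutants at 4 months, S427 had a HOX sum of 100 CPM (24.3 to 35.5) and 39.5% of its counts in the 10 most abundant genes (19.9 to 22.7).

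Genotype effects differed between groups by the interaction tests. Between ages in mDA neurons 580 genes had a more positive and 362 a more negative effect at 8 months, among them Slc18a2 (-1.28), Slc6a3 (-1.56), Th (-1.10), Nr4a2 (-0.71), En1 (-1.54), Arhgap6 (-1.95), Fam184a (-1.66), Gad1 (1.97), Pax6 (3.52), Hoxd11 (7.68), Slc6a5 (5.41) and Wnt5a (1.83). Between ages in 5HT neurons 0 genes had a more positive effect by edgeR (DESeq2 15, voom 2; 620 genes at an unadjusted p under 0.05) and 2 a more negative one, Slc6a4 (-2.51) and Tph2 (-2.62). Between cell types 10 genes had a more positive and 37 a more negative effect in mDA, among them Gata2 (3.39), Fev (3.05), Bcam (2.36), Stxbp2 (1.41), Sympk (0.80), Nr4a2 (-2.76), Tle2 (-2.30), Ret (-1.67), Lama5 (-1.59) and Tradd (-4.11). The differences for Nr4a2 and Tradd include the rises in 5HT neurons given above. Outside the tests, the reporter had more than 3 counts in 48 libraries.

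In mDA mutants at 8 months dopaminergic identity genes were lower and some markers of other cells higher. A lower share of dopaminergic neurons that raised all other markers alike would leave the ratio of GABA to microglia markers unchanged. The log2 ratio differed by 1.17 (exact permutation p = 0.00109, 12870 regroupings that ignored sequencing set and sex), which argues against that form alone. The 2 lists were picked after their results were known. A lower share filled mainly by GABA neurons would shift this ratio too, so the test cannot decide on it. RNA from astrocytes and endothelial cells that lack these transcripts would lower Ddc with Slc6a3, Slc18a2 and Th. The log2 ratio of Ddc to their mean differed by 1.01 (exact permutation p = 0.000155, the smallest these regroupings can give). The contrast was picked after Ddc was seen to fall less, and whether the added cells hold Ddc was not tested. This ratio therefore cannot decide on that source. With the marker level as a term 4 of 10 identity genes were called and 87.9% of their median change was kept (-1.07, SE 0.147, before and -0.941, SE 0.201, after). Calls ended mainly through larger errors, the marker level differing by 1.57 SD between genotypes. The change kept argues against RNA that these markers track as the whole source of the fall of the 10 genes. They were, however, chosen by their fall in the same libraries. RNA from GABA neurons may add to the gain of Gad1 (240 CPM) and Gad2 (55.3 CPM, from 115 in wt). Were it the only source, Gad2 was predicted to gain at least as many CPM as Gad1, and it gained fewer. The ratio of Gad1 to Gad2 in any added cells was not measured, so this cannot decide. RNA from GABA neurons cannot be told apart from a change within the sorted neurons, since no sorted GABA neurons were analysed here. A genotype effect on the dopaminergic neurons stays open, as does a lower share of them filled mainly by GABA neurons.

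In mDA mutants at 4 months 92 genes were called lower. The 4 set1 mutants alone could account for them, but the test at hand used a different set of genes. The 1281 genes called lower within set1 differed by -1.2 there and by a mean of -0.0776 in sets 2 and 3 (exact permutation p = 0.629, 420 regroupings within sets, -0.34 in set2, 0.185 in set3). They were chosen by their fall within set1, so a smaller difference elsewhere follows in part from that choice, and the test cannot decide. The 92 genes kept 71.1% of their median change without these libraries and all stayed negative (higher calls 93.4%), but the remaining libraries had helped to choose them. With the share of counts in the 10 most abundant genes as a term 5 of the 92 were called and 75.4% of their median change was kept (ratio of standard errors 1.01); the mean share was 36.2% in set1 mutants, 28.6% in set1 wt and 22.2% to 24.5% elsewhere, so this share and the set1 mutants cannot be told apart. A genotype effect that differs between sets, and sex, which equals genotype in set1, stay open.

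Myo7a was lower in mDA mutants at both ages and lies 8.1 Mb from Eed. Inherited sequence around the edited gene may contribute at 4 months, but the tables leave this open: 10 genes within 20 Mb of Eed were called (4.39% against 1.14% elsewhere, Fisher's exact p = 0.000399). Of the 10, 7 were lower (p = 0.00041; 0.154 for higher), the class that the set1 mutants could account for, and of the genes near Eed called at both ages Myo7a kept its direction while Sec11a turned from -0.75 to 0.81. At 8 months 11 were called (4.82% against 4.27%, p = 0.386), which gives this no support there. An effect of Eed on Myo7a stays open.

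In the planned splits the real split gave the most calls for mDA at 4 months (181 calls, highest other split 1, 1 of 100 splits as large). The same held for mDA at 8 months (666, other 50, 1 of 100) and 5HT at 8 months (62, other 1, 1 of 35). It also held for mDA genotype by age (580 and 362, other 413 in all, 1 of 100), genotype by cell type (47, other 10, 1 of 50) and the wt cell types (3513, other 0, 1 of 100). Labels were regrouped without regard to sequencing set or sex, and the other splits mixed the real groups. A part of set or sex in these counts is therefore not excluded. For 5HT at 4 months another split gave as many calls (2 calls, highest other 2, 2 of 35 splits as large), so chance was not excluded. For 5HT genotype by age 3 of 100 splits were as large as the 2 calls, but another split gave 25, several times the real count. This, like the 21 calls of a split of wt mDA ages against 0, points to some structure of the samples, which was not traced. The 413 calls of a split of mDA genotype by age may point to it too, as may the 50 of a split of mDA at 8 months. In the latter 12 of 16 labels were as in the real split. For age in wt, 100 of 100 mDA splits (0 calls by edgeR, highest other 21) and 35 of 35 5HT splits (0, other 0) were as large, with 1204 and 964 genes at an unadjusted p under 0.05, 18 and 15 calls by DESeq2 and 0 and 2 by voom.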

How the results depend on the processing

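The settings that left out named libraries other than 1 at a time, used library totals, or added the top-10 share or the marker level were chosen after the data were seen. Of the named called genes, 35 of 36 in mDA at 4 months, 80 of 80 in mDA at 8 months, 2 of 2 in 5HT at 4 months and 29 of 29 in 5HT at 8 months kept their direction in every setting run, and 1, 24, 0 and 17 also kept their call. Every setting reused all or part of the libraries that chose these genes. Main counts of calls, higher and lower, were 89 and 92 (mDA 4 months), 376 and 290 (mDA 8 months), 2 and 0 (5HT 4 months), 39 and 23 (5HT 8 months), 580 and 362 (mDA genotype by age), 0 and 2 (5HT genotype by age), 10 and 37 (genotype by cell type), 1835 and 1678 (wt cell types) and 0 and 0 (age in wt). The 1.5-fold test lowers counts by construction. Settings with fewer libraries lowered some counts and raised others, and why was not tested. No paired analysis was possible because no replicate numbers are shared between groups. Depth put 3 counts at up to 1.82 CPM, so genes near that level were not resolved.

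Counts below are given as higher and lower. DESeq2 made more false calls than edgeR or voom on the simulated data. With DESeq2 they were 206 and 146 (mDA 4 months), 580 and 480 (mDA 8 months), 40 and 8 (5HT 4 months), 124 and 52 (5HT 8 months), 721 and 650 (mDA genotype by age), 15 and 13 (5HT genotype by age), 56 and 121 (cell type), 15 and 3 (mDA age) and 11 and 4 (5HT age). Its shared calls were 17 higher between 5HT ages (0 by edgeR), 8 higher and 1 lower between cell types at 4 months (0 and 0) and 81 higher and 11 lower at 8 months (33 and 4). With voom they were 113 and 44 (mDA 4 months), 766 and 668 (mDA 8 months), 1 and 0 (5HT 4 months), 206 and 88 (5HT 8 months), 729 and 638 (mDA genotype by age), 2 and 9 (5HT genotype by age), 11 and 22 (cell type) and 0 and 2 (5HT age). Under voom Cdkn1a turned to 0.079 (mDA 4 months, -0.050) and Slc6a3 to 0.044 (5HT 4 months, -0.43). Without the sex term they were 81 and 45 (mDA 4 months), 231 and 162 (mDA 8 months), 66 and 88 (mDA genotype by age), 3 and 0 (5HT 4 months) and 1 and 0 (5HT age), and Cdkn1a turned to 0.066. Against a 1.5-fold change they were 21 and 1 (mDA 4 months), 134 and 56 (mDA 8 months), 34 and 27 (mDA genotype by age), 1 and 0 (5HT 4 months), 29 and 6 (5HT 8 months), 4 and 8 (cell type) and 837 and 416 (wt). Without a filter they were 68 and 61 (mDA 4 months), 11 and 1 (5HT 4 months), 1 and 4 (5HT genotype by age) and 2 and 0 (5HT age).

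A shared batch label gave 66 and 39 (mDA 4 months). No batch term gave 44 and 13 (mDA 4 months) and 347 and 268 (mDA genotype by age), with Ddc at -0.016 (0.051). The compared groups alone gave 229 and 154 (mDA 8 months), 0 and 0 (5HT 4 months) and 140 and 59 (5HT 8 months), with Cdkn1a at 0.064 and Tph2 at 0.0062 (mDA 4 months, -0.044). Detected genes as a term gave 68 and 50 (mDA 4 months). Set1 alone gave 788 and 1281 (mDA 4 months) and 249 and 156 (mDA 8 months), with Cdkn1a at 0.056 and Gad1 at -0.14 (4 months, 0.79). Set2 alone gave 5 and 0 (mDA 4 months) and 68 and 24 (mDA 8 months). With it Ddc was -0.057, Nr4a2 -0.13 (0.18), Pitx3 0.47 (-0.20) and Tph2 0.21 at 4 months, and Tph2 was -1.12 at 8 months (0.17). Without the set1 mutants there were 19 and 1 (mDA 4 months) and 36 and 53 (mDA genotype by age), with Cdkn1a at 0.21, Ddc at -0.042, Nr4a2 at -0.092, Pitx3 at 0.13 and Slc6a3 at -0.018 (0.16). The top-10 share as a term gave 33 and 5 (mDA 4 months), 183 and 120 (mDA 8 months), 12 and 3 (5HT 4 months) and 72 and 49 (5HT 8 months). With it Pitx3 was 0.0049 and Tph2 0.27 (mDA 4 months) and Tph2 -0.67 (mDA 8 months). Without S369 and S427 there were 10 and 2 (5HT 4 months), 84 and 52 (5HT 8 months) and 1 and 4 (5HT genotype by age), with Slc6a3 at 0.14 and 0.0050. The marker term gave 129 and 79 (mDA 8 months), with Cdkn1a at 0.083 (-0.25).

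At adjusted p under 0.01 the mDA ages shared 26 higher and 1 lower (44 and 2) and the cell types at 8 months 13 and 2 (33 and 4). With an estimated correlation 4, 8 and 1 lists passed (9, 15 and 3 at the preset one) in mDA at 4 and 8 months and 5HT at 4 months, and the mDA- and 5HT-enriched genes were at adjusted p = 0.135 and 0.141 in mDA at 4 months. With lists at a log2 fold change over 1 the 5HT-enriched median turned to -0.194 in mDA at 4 months (adjusted p = 4.73e-06) and -0.0444 in 5HT at 4 months. With RLE scaling the direction of the oligodendrocyte precursor list in mDA at 4 months turned (adjusted p = 0.972), and calls were 96 and 56 (mDA 4 months), 481 and 449 (mDA genotype by age) and 3 and 0 (5HT 4 months). Library totals moved the median of all genes by 0.12 in mDA genotype by age and gave 857 and 251 there, 506 and 210 in mDA at 8 months and 1 and 0 in 5HT at 4 months.

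Leaving out each 5HT library in turn gave 0 to 4 calls higher and 0 lower at 4 months, and 17 to 53 higher and 10 to 33 lower at 8 months. It gave 0 higher and 2 to 3 lower for genotype by age, and 0 to 1 higher and 0 lower for age. Log2 fold changes ran from -0.98 to 6.23 for Cdkn2b, -0.27 to 0.13 for Slc18a2 and -0.78 to 0.37 for Slc6a3 at 4 months, and from -1.28 to 0.17 for Slc6a3 and -0.52 to 0.25 for Th at 8 months.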

Other observations

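The comparison of Xist between females was chosen after values were seen. Polycomb genes outside the comparisons described moved in few cases. In mDA neurons at 8 months 3 of 21 PRC1 genes rose and 0 fell, among them Pcgf1 (24.4 ± 9.92 to 70 ± 23.4 CPM, 1.54) and Cbx8 (1.46), or 3 when adjusted over the list alone. Of 12 PRC2 genes 0 were called in any of the 4 genotype comparisons by edgeR (1 rose when adjusted over the list alone in mDA and 1 in 5HT at 4 months). Of 37 signalling ligands of the WNT, BMP and hedgehog families, Wnt5a (40.9 ± 11.7 to 125 ± 22 CPM, 1.68) and Lef1 (1.90), a nuclear effector, rose in mDA neurons at 8 months (3 rose and 1 fell when adjusted over the list alone; adjusted p = 0.0164 with an estimated correlation), and 0 were called at 4 months (1 rose when adjusted over the list alone) or among 32 in 5HT neurons at 8 months (list adjusted p = 0.038, or 0.112 with an estimated correlation). Pmaip1, a p53 target that promotes cell death, rose from 1.11 ± 1.37 to 12.4 ± 5.8 CPM in mDA neurons at 8 months (4.00, adjusted p = 0.00186), the 1 called of 31 cell death genes (1 when adjusted over the list alone), and 0 of 31 were called at 4 months (1 rose when adjusted over the list alone) and 0 of 34 in 5HT neurons at 8 months. Of 16 familial parkinsonism genes 0 were called by edgeR in mDA neurons at either age.

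Of 71 nuclear oxidative phosphorylation genes, Atp5g1 (-0.58) and Cox6c (-0.50) fell in mDA neurons at 4 months (23 fell when adjusted over the list alone; median -0.34, adjusted p = 0.198 with an estimated correlation), and Atp5a1 (0.57) and Atp5b (0.62) rose at 8 months (0 when adjusted over the list alone; median 0.32, 0.444). In 5HT neurons 0 were called at 4 months (median -0.15, adjusted p = 0.795 with an estimated correlation) and 0 at 8 months (0 when adjusted over the list alone). Of 18 imprinted genes Igf2 (2.76) and Zdbf2 (0.87) rose and Peg3 (-0.47) fell in mDA neurons at 8 months (2 and 1 when adjusted over the list alone), and 0 were called at 4 months (3 rose and 1 fell when adjusted over the list alone). The 4 ependymal and choroid markers, the 2 glutamate markers, the 2 noradrenergic and cholinergic markers, the 1 erythroid gene and the 6 sex check genes tested in mDA neurons had 0 calls at both ages (adjusted over each list alone, 1 glutamate marker fell at 4 months and 1 rose at 8 months, and 1 noradrenergic and cholinergic marker fell at 8 months), and no mitochondrially encoded gene was tested (0 members). Of 11 serotonin synthesis and handling genes in mDA neurons 0 were called at 4 months (1 fell when adjusted over the list alone) and Slc18a2 fell at 8 months (3 when adjusted over the list alone). At 8 months 6 of 10 substantia nigra type and 1 of 14 ventral tegmental type markers fell in mDA neurons (Fisher's exact p = 0.00884). This test treats genes as independent, although members of each list varied together in the same animals (estimated correlation 0.114 and 0.202). Its p-value therefore does not measure a difference between animals.

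Called genes differed in their wt level at the other age. In part this follows from detection, since a gene near the floor in wt can hardly be called lower. In mDA neurons at 8 months the median was 16.7 CPM for genes called higher, 23.7% of them under 1 CPM, 74.1 for genes called lower and 22.0 for all genes tested. In 5HT neurons at 8 months it was 0.543 CPM for higher calls, 59.0% under 1 CPM, 139 for lower calls and 20.7 for all. Xlr3a (1.49 at 4 months, 2.19 at 8 months), Xlr3b and Xlr3c were called higher in mDA mutants; they were named after their values were seen, and which of these near-identical copies the reads came from was not resolved here. In females of the mDA groups, Xist was 4869 ± 681 CPM in 6 mutants and 2179 ± 300 in 4 wt at 4 months (exact permutation p = 0.00476, the smallest that 210 regroupings can give). The regroupings ignored the sequencing set, which was partly confounded with genotype: 4 of these mutants were set1, and the 4 wt were set2 or set3. Within set2 the unscaled values were 4169 and 4624 in mutants and 2262 and 1749 in wt. At 8 months Xist was 3324 ± 323 in 4 mutants and 2766 ± 803 in 3 wt (p = 0.257). In 5HT females it was 2605 ± 797 in 2 mutants and 1997 ± 129 in 2 wt at 4 months (p = 0.667), and 2911 ± 516 in 2 mutants and 2373 ± 47.6 in 3 wt at 8 months (p = 0.1, the smallest that 10 regroupings can give; at 4 months 6 regroupings cannot give under 0.333).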
